A study of Rattus norvegicus with 6 samples.

How the data were processed

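Messenger RNA was sequenced from cultured rat aortic smooth muscle cells (RASMC), the contractile cells of the artery wall, in 6 libraries. Of these, 3 came from cells labelled wild type with no treatment (control) and 3 from cells with knockdown of H2a.z, a replication-independent variant of histone H2A, that had also been given cholesterol. Groups and replicate numbers were taken from the sample titles. The labels give the same batch, day 2, to all 6 libraries and do not say whether this names a sequencing batch or a time. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The dose and duration of cholesterol and the knockdown method are not given in the sources used here.

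The polyadenylated RNA was purified, fragmented and amplified, and libraries were made with a Yeasen kit for Illumina sequencing, per the labels' protocols. The deposited values are raw read counts per Ensembl rat gene ID, 1 file per library, with no normalization. fastp, STAR and HTSeq and the rat genome build rn7 are named in the submitters' processing notes, without versions. The order of steps, the annotation release and the strand setting of the counting are not given in the sources used here. Each file holds 30562 gene IDs, followed by the counter's summary lines for reads that overlap no annotated feature, reads that overlap more than one gene, and reads aligned to several places. These lines name no gene and stayed out of library sizes and tests. They held 13.7% to 15.8%, 3.09% to 3.51% and 1.86% to 2.33% of the reads in the control files. In the knockdown plus cholesterol files they held 7.04% to 7.29%, 3.94% to 4.01% and 2.22% to 2.70%. Unaligned reads are given as 0 in every file, so shares are of the reads listed in a file and not of all reads sequenced. Reads that fit several places or several genes were not assigned to a gene, so genes with near-identical copies or overlapping neighbours can be undercounted.

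The gene IDs could not be paired with symbols here. The gene table used (RefSeq, assembly GRCr8, 47357 rows) held an Ensembl ID in 0 rows, and 0 of the 30562 IDs matched it. As a result the H2A.Z genes themselves, 24 gene lists fixed before the data were examined (contractile, cholesterol, macrophage, matrix, cell cycle and other groups, with markers of other cell types) and the planned gene set tests were not analysed here. No coordinates or gene lengths were used. The naming rule fixed before the data were examined asked for an adjusted p under 0.05, at least 10 CPM (counts scaled by library size, as defined by edgeR) in the higher group, all 3 libraries of one group above all 3 of the other, and a symbol. It named the 10 largest changes each way, the 10 smallest p-values and members of each list. Without symbols, the 2 IDs with the largest fold each way that met the other criteria are printed.

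Counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Genes were kept by edgeR's expression filter with its default minimum count of 10 and minimum total of 15, which left 13252. Libraries were scaled by TMM, and a robust quasi-likelihood model with group as its 1 term was fitted to the 6 libraries. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. The standard error (SE) of a log2 fold change was taken from the fitted coefficient and its F statistic. It can understate the error for genes near 0 reads in a group, so it is not given for the printed IDs. CPM values use TMM-scaled library sizes, and correlations and principal components use log2 CPM with a prior count of 2. Shares of reads were compared by an exact permutation test, two-sided, which cannot give a p below 0.1 for 3 libraries against 3. For a gene with 0 reads in a group, the limit is 3 reads over the group's 3 libraries. For ratios with few reads, 95% intervals are exact conditional Poisson intervals on reads summed per group. Such intervals and limits cover counting error only.

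The test was tried on simulated counts for the 13252 genes. They were drawn from each gene's mean over the 6 libraries, the fitted dispersions and the real library sizes. With 200 genes changed, 58 of the 100 changed 1.5-fold and 86 of the 100 changed 2-fold were recovered in the right direction. There were 16 false calls among the other 13052 genes. Set against the 58 and 86 genes recovered, these false calls were a larger share of the calls than the adjusted p threshold aims for. With no gene changed there were 0 calls. With 9694 genes moved by the folds fitted in the real comparison, 92.8% were recovered, 4.05% of the unmoved genes were called, and 0 were called in the wrong direction. The 9694 moved genes were those already called, moved by their own fitted folds, so high recovery was partly built in. Their starting level was the mean over both groups, so genes near 0 reads in a group were simulated at higher counts than the real ones. The simulation gave both groups the same dispersion per gene and drew genes independently. The real controls spread more than the other libraries, mostly through control replicate 2, so these rates may not hold for the real data.

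No pair of libraries agreed within sampling noise. The chi-square statistic per degree of freedom, over genes with at least 10 reads in the pair, was 2.76 to 4.45 for the 3 pairs within knockdown plus cholesterol. It was 3.45 for control replicates 1 and 3, 30.5 for control replicates 1 and 2, and 28.9 for control replicates 2 and 3. Alternatives covered the scaling, the tool (DESeq2 1.42.0 with its own independent filtering, limma-voom), the filter on low counts, the replicate number as a block, equal depth, the dispersion estimate, the threshold, and leaving out each library. Leaving out the 20 most abundant genes, and taking library size from all reads in a file without TMM, were added after seeing the data. The planned variant that also left out mitochondrially encoded genes, and the variants of gene list tests, were not run for want of gene names.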

Results

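The transcriptome of rat aortic smooth muscle cells was measured by RNA sequencing in 3 control libraries and in 3 libraries from cells with H2a.z knockdown and added cholesterol. The control files held 15581152 to 17834401 reads assigned to genes, and the knockdown plus cholesterol files 16887348 to 18196937. Of 30562 annotated genes, 10689 had no read in any library and 13252 were abundant enough to test. The libraries allow 1 comparison, knockdown plus cholesterol against control. It addresses how the expression program of cells labelled with H2a.z knockdown and given cholesterol differs from that of untreated wild-type cells. The control cells had neither, so the comparison does not isolate knockdown under cholesterol loading. Knockdown alone and cholesterol alone were not analysed here, so the changes described here cannot be assigned to either. Differences in culture or library quality between the groups are not separated from them. The level of the H2A.Z genes was not analysed here, because the gene IDs could not be paired with symbols, and the knockdown is therefore taken from the label.

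Most of the tested transcriptome differed between the groups. Of the 13252 genes, 9694 (73.2%) changed, with 4807 genes higher and 4887 lower after knockdown and cholesterol (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The near balance of the directions (49.6% of the changed genes higher) is largely set by the scaling between libraries, which centres the folds near 0. It is not a finding about the cells. With library size from gene reads and no TMM, 47.8% of the changed genes were higher. The median log2 fold change was 0.83 among the genes that rose and -0.85 among those that fell, against a median standard error of 0.12 over all tested genes. A further 3558 genes did not pass the test. All 3 libraries of one group lay above all 3 of the other for 10282 genes (77.6%). For a single gene, random labels would give this with a probability of 10%. Genes in the same libraries can move together, so the contrast of these shares is not a test of chance.

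Large changes were a minority of the calls. Of the 9694 changed genes, 3836 differed at least 2-fold (1847 higher and 1989 lower), and 3005 differed by less than 1.5-fold. Changes of at least 4-fold were found in 1033 genes, of which 481 rose and 552 fell. At least 8-fold changes were found for 216 genes that rose and 181 that fell, and at least 16-fold changes for 100 that rose and 59 that fell. These are fitted folds, which for genes near 0 reads in a group depend on the model's prior count. Tested against a fold of 1.5 rather than against no change, 4943 genes passed.

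**Figure D1:**
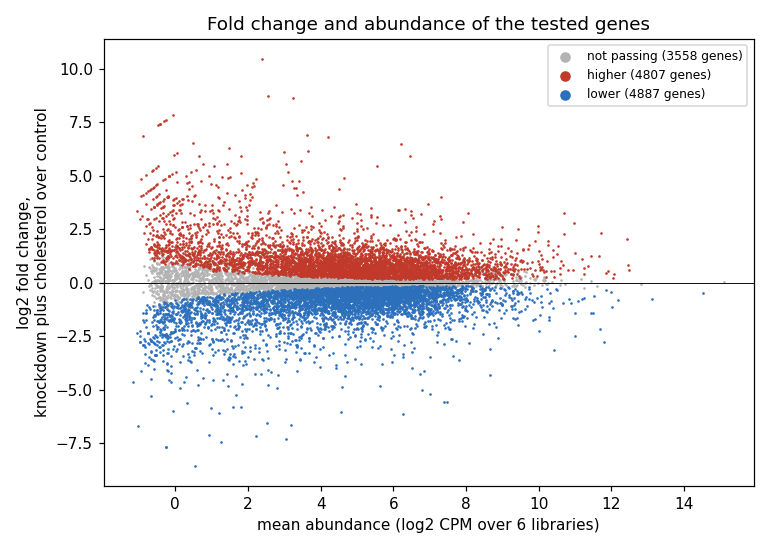
Each point is a tested gene, with its mean abundance over the 6 libraries (log2 CPM) on the horizontal axis and its log2 fold change, knockdown plus cholesterol over control, on the vertical axis. Genes that rose (4807, red) and fell (4887, blue) lie on both sides of 0 over most of the range of abundance, and 3558 genes (grey) did not pass the test.

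Genes changed at all levels of expression. The tested genes were divided by mean abundance into 3 classes of equal size. In the most abundant class (median 90.5 CPM), 1756 rose and 1707 fell, so that 78.4% changed at this scaling. In the middle class (median 23.0 CPM), 1644 rose and 1659 fell, or 74.8% of the genes together. In the least abundant class (median 3.22 CPM), 1407 rose and 1521 fell, which is 66.3%. Changes of at least 2-fold were called for 42.8% of the genes in the least abundant class, 23.8% in the middle class and 20.2% in the most abundant class. The median standard error of the log2 fold change was 0.23, 0.11 and 0.08 in these classes, so the weakly expressed genes were also the least precisely measured.

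The most abundant transcripts took part in the change. The 100 most abundant genes of the control and the 100 most abundant of the knockdown plus cholesterol cells had 66 genes in common. Of the 100 in control, 52 fell, 27 rose and 21 did not pass, and 31 changed at least 2-fold. Of the 100 after knockdown and cholesterol, 61 rose, 21 fell and 18 did not pass, and 34 changed at least 2-fold. The genes called higher held 29.1% ± 1.73 of the gene reads in control and 50.3% ± 0.33 after knockdown and cholesterol (SD, n = 3). The genes called lower held 47.2% ± 1.88 and 25.8% ± 0.26 (SD, n = 3). These shares describe genes chosen by the same test and are not independent evidence of it. Choosing genes by their level in one group also favours genes higher there, so part of the excess of falls in the first set and of rises in the second comes from the choice. The 10 most abundant genes of each library together held 11.5% ± 0.72 of the gene reads in control and 10.6% ± 0.19 after knockdown and cholesterol (SD, n = 3).

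Some genes went from near absence to a mean of at least 1 CPM or the reverse. With at most 3 reads over a group's 3 libraries taken as near absence, 38 genes were near absent in control and at a mean of at least 1 CPM after knockdown and cholesterol. The reverse held for 16 genes. Of these, 3 genes reached at least 10 CPM after knockdown and cholesterol, and 0 genes near absent there had been at 10 CPM or more in control. The naming criteria other than the symbol were met by 3657 genes that rose and 3637 that fell, and the 2 with the largest fold each way are given here by Ensembl ID. ENSRNOG00000002968 had 0 reads in the 3 control libraries and 10.1 ± 1.03 CPM after knockdown and cholesterol (SD, n = 3), from 531 reads. Its mean was 169 times the limit that 3 control reads would set (0.0597 CPM), and by the 95% counting interval used for the other 3 IDs it was at least 137-fold higher (edgeR adjusted p = 1.92e-07). ENSRNOG00000003866 had 1 read over the control libraries and 11.3 ± 1.60 CPM after knockdown and cholesterol (SD, n = 3). Its ratio was 562, with a 95% counting interval of 102 to 22506 (edgeR adjusted p = 3.46e-08). The 1 read lies in control replicate 1, and without that library, with 0 control reads left, the fitted log2 fold change of ENSRNOG00000003866 moved from 8.70 to 10.61. ENSRNOG00000005792 fell from 16.3 ± 0.59 CPM to 0.094 ± 0.11 CPM (SD, n = 3), a ratio of 174 with an interval of 73.2 to 530.0 (log2 fold change -7.32, edgeR adjusted p = 2.56e-08). Of its 5 reads after knockdown and cholesterol, 4 lie in replicate 3, and without that library the log2 fold change of ENSRNOG00000005792 was -8.81. ENSRNOG00000052952 fell from 17.9 ± 1.77 CPM to 0.17 ± 0.094 CPM (SD, n = 3), a ratio of 106 with an interval of 54.8 to 229.1 (log2 fold change -6.65, edgeR adjusted p = 1.13e-08).

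The libraries separated by group. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.986 to 0.994 between libraries of the same group and 0.881 to 0.909 between groups. The first principal component carried 89.6% of the variance and placed the control libraries at -71.9 to -57.5 and the others at 60.7 to 65.3. Control replicate 2 stood apart on the second component (4.76% of the variance), at -28.0 against 16.2 and 14.8 for the other control libraries. The biological coefficient of variation was 12.9% among the 3 controls and 4.44% without control replicate 2, against 4.76% among the knockdown plus cholesterol libraries. Without control replicate 2, 10370 genes changed.

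How reads fell on the annotation also moved with the group. Reads outside annotated features made up 14.5% ± 1.17 of the reads in the control files and 7.15% ± 0.13 in the knockdown plus cholesterol files (SD, n = 3). Reads assigned to genes made up 80.1% ± 0.75 and 86.5% ± 0.17 (SD, n = 3). For both measures the groups did not overlap, and the exact permutation test (two-sided) gave p = 0.1, the smallest it can give with 3 libraries against 3. Control replicate 2 had the highest share outside features, 15.8%, against 13.9% and 13.7% in control replicates 1 and 3. The group difference in gene expression and the difference in reads outside features separate the same libraries. With library size taken from all reads in a file and no TMM, 5255 genes rose and 4447 fell, and with gene reads and no TMM, 4633 rose and 5066 fell.

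**Figure D2:**
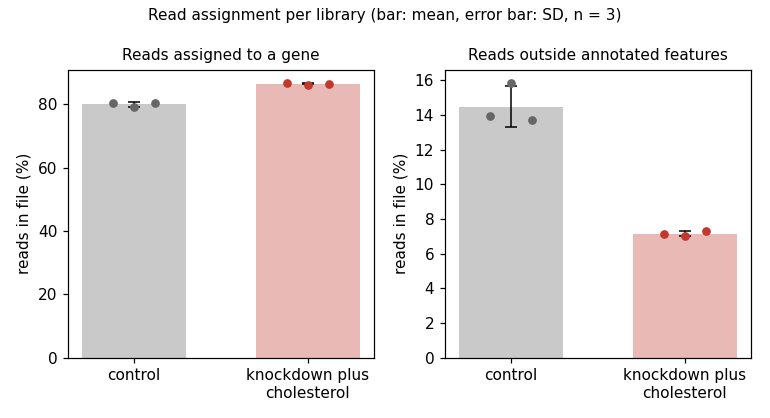
Bars give the mean share of the reads in a file (%) that were assigned to a gene (left) or lay outside annotated features (right), error bars the SD and points the 3 libraries of each group. The control libraries hold 13.7% to 15.8% of their reads outside features, and the knockdown plus cholesterol libraries 7.04% to 7.29%.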

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

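The tests on read assignment in this part were chosen after the result was seen. Reads that overlapped more than one gene, which enter no comparison above, made up 3.97% ± 0.035 of the reads in the knockdown plus cholesterol files and 3.36% ± 0.24 in the control files (SD, n = 3), and every knockdown plus cholesterol library lay above every control library. A smaller share of reads outside features would by itself raise this share. Taken as a percent of gene reads, which removes that dilution, the share was still 0.39 percentage points higher, 4.59% ± 0.036 against 4.20% ± 0.26 (SD, n = 3), and the groups did not overlap. The exact permutation test (two-sided) gave p = 0.1, the smallest it can give here. The raw share was flagged for its lack of overlap, so the lack of overlap here is not independent of that choice. Without control replicate 2 (3.89%), the control mean was 4.35% and the difference 0.24 percentage points, still without overlap. This argues against dilution as the whole cause. Higher expression of genes with overlapping neighbours was not tested and may contribute.

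The share of reads outside annotated features was about 2 times as high in control (14.5% against 7.15%). Genomic DNA in the control libraries was one candidate source, since it would also place reads on silent genes. The 17310 genes too weak to test were compared after thinning all libraries to equal gene reads. They held 33115 reads in the control libraries and 33370 in the others. Of those read in 1 group only, 46.8% were read in control (95% exact binomial interval 44.9% to 48.6%), where genomic DNA by itself would put more than 50%. The weak genes thus showed no excess in control. The interval treats genes as independent, and per library their share of gene reads did not separate the groups (exact permutation test, two-sided, p = 0.5). Weak genes that rose after knockdown and cholesterol would also lower the control share, so genomic DNA is not excluded. Unspliced or unannotated transcripts, and an effect of the knockdown or of cholesterol on them, stay open as well, since they need the alignments.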

How the results depend on the processing

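The count of changed genes stayed within 1.5 times 9694 under 18 of 19 alternatives. The exception was the test against a fold of 1.5 (glmTreat), which passed 4943 genes (2391 higher and 2552 lower), as that test asks for more than a difference from 0. In most settings fewer genes were tested than the upper bound on the count changed, so only a fall could have crossed it. Apart from glmTreat, the counts higher and lower stayed within 1.5 times, at 4033 to 5255 and 4193 to 5249 genes, and the count at least 2-fold did so under all 19, at 2729 to 4620. The 2 threshold settings were applied to the counts higher, lower and at least 2-fold and to single genes after seeing the data. DESeq2, run with its own independent filtering on the 19873 genes with at least 1 read in place of the filter on low counts, called 9600 genes and kept 93.8% of the calls in the same direction. limma-voom, with the filter unchanged, called 9716 and kept 99.4%. No alternative called a gene of the 9694 in the opposite direction. Leaving out 1 library at a time gave 8948 to 10370 genes, the highest without control replicate 2. The share of changed genes that were higher ran from 47.8% to 54.2% over the alternatives, and the median log2 fold change of all genes from -0.036 to 0.075, both extremes coming from scaling by library size, with gene reads and with all reads in a file, both without TMM. The 4 printed IDs kept their direction and passed in each of the 19 alternatives, the largest adjusted p being 1.18e-05 (DESeq2, edgeR or limma). The fitted log2 fold changes moved more: limma-voom gave 8.40 for ENSRNOG00000002968, against 10.44 by edgeR, and 8.03 for ENSRNOG00000003866, against 8.70, and leaving out 1 library gave up to 10.61 for the latter (without control replicate 1) and -8.81, against -7.32, for ENSRNOG00000005792 (without knockdown plus cholesterol replicate 3). With the replicate number as a block, 9486 genes changed. The numbers were not treated as pairs because the labels do not state that they pair samples. Same-numbered libraries did not deviate together (correlations of 0.068, -0.0023 and -0.12), and 1 of 6 libraries correlated best with its own number. With 3 libraries per group this check cannot exclude pairing. In the least abundant class (median 3.22 CPM) 1490 genes did not pass, with a median SE of 0.23, against 954 genes and 0.08 in the most abundant class. Whether depth, spread between libraries or absence of change kept them from passing was not tested.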

Other observations

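The split test and the count at equal depth were planned, whereas how to judge the count at equal depth, and the other tests in this part, were chosen after the result was seen. The breadth of the change, 9694 of 13252 genes, was weighed against technical explanations. Thinned to equal depth, the libraries gave 9563 genes. The groups already overlapped in gene reads (15581152 to 17834401 in control, 16887348 to 18196937 in the others). Thinning thus removed few reads and could hardly have changed the count, so it weighs little against depth as a cause. If a few abundant genes had distorted the scaling and so made the calls, some other factor between the groups would end most of them. With the scaling of the knockdown plus cholesterol libraries multiplied by factors from 0.5 to 2, the fewest genes changed were 9693, which argues against such a distortion as the cause of the breadth. The numbers higher and lower did depend on the factor (10163 and 1172 at 0.5, 983 and 10131 at 2). Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave as many changed genes, and likewise 1 for the genes higher, lower and changed at least 2-fold. The highest other split gave 0 genes for each, against 9694, 4807, 4887 and 3836, and 10 splits are too few for a share under 0.05. Each other split mixes the groups on both sides, so the group difference itself widens the spread within each side. Few calls were therefore possible whatever its cause, and the 0 does not estimate false calls. A gradient in library quality, marked by the reads outside features, could also run along the group difference. If it did so in proportion, control replicate 2, which has the most such reads, would deviate from the other controls away from the knockdown plus cholesterol libraries with a slope over genes of -0.30. The slope was -0.071, in that direction but smaller, and rests on 1 library, so a contribution of such a gradient cannot be told apart from the group difference. Knockdown, cholesterol and any difference in culture between the groups stay open as well, as untested.

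Control replicate 2 set most of the spread among the controls. The biological coefficient of variation was 15.6% without control replicate 1, 15.7% without control replicate 3 and 4.44% without control replicate 2.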
